A study of Mus musculus with 10 samples.

How the data were processed

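Superior cervical ganglia of male B6.FVB-Tg(Npy-hrGFP)1Lowl/J mice, in which Npy sequences drive a humanised Renilla GFP, were dissociated with collagenase and trypsin and kept for 1 h in medium with nerve growth factor and ara-C, per the labels' protocols. Cells were then sorted by hand into pools of 10, lysed without RNA purification, amplified as cDNA with the Ovation One-Direct system, labelled with biotin and hybridised to Illumina mouse BeadChips. The 10 arrays fall into 5 GFP-positive and 5 GFP-negative pools of 6 mice. Per the array names, the pools of 4-month mice (1, 2 and 3) lay on BeadChip 1 and those of 7-month mice (4, 5 and 6) on BeadChip 2.

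The deposited non-normalized intensities are bead-summary values on a linear scale, 1 per probe and array, without normalization between arrays, per the file headers and the values, whose medians differ between arrays (89.2 to 96.2). BeadStudio is named in the submitters' processing notes without a version, and any step before the summary is not given in the sources used here. The deposited detection p-values compare each probe with the negative control beads of its array, per the file headers, which place a column of them after each array. A second deposited table holds intensities that, read from the values, the authors had quantile normalized between arrays on a linear scale. Its median was 91.1 in all 10 columns, and each column kept the rank order of its array in the other table (Spearman's rho across probes 0.99998, a comparison across probes, which are not independent replicates). Whether that table had also been scaled, centred or background corrected in another way is not given in the sources used here. No column without a sample of its own was found, and both tables hold 45281 probes.

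Gene symbols came from the platform's annotation table and were checked against a RefSeq gene table (GRCm38.p6) by Entrez identifier. Of the probes, 34885 had 1 symbol, 18 had several and 10378 had none, and probes with several or no symbol were tested under their own identifiers as unnamed. Among the single symbols, 34807 matched by identifier and 0 had to be renamed. The gene assigned to a probe was not checked by aligning its sequence, and the report gives differences by GFP and by age at a gene's other kept probes beside the one used. Other probes were not compared for the interaction.

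The non-normalized intensities were background corrected with the detection p-values (nec), given an offset of 16, put on a log2 scale and quantile normalized in limma 3.58.1 under R 4.3.3. Probes detected at a detection p under 0.01 on at least 3 of 10 arrays were kept (7368 probes), and each gene was represented by its kept probe with the highest mean, which left 4459 named genes and 1775 unnamed probes, 6234 in all. Linear models were fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold an adjusted p under 0.05). GFP-positive and GFP-negative pools were compared with BeadChip as a covariate. Ages were compared with GFP status as a covariate and the mouse as a random block (duplicateCorrelation). An interaction term tested whether the GFP difference differed between ages. Npy was also compared by an exact two-sided permutation test over all splits of the arrays into 5 and 5. Log2 intensities in the text are on this corrected and normalized scale, means carry the SD between pools and fitted differences their standard error. A gene detected in no pool of a group has no measured fold change, and a lower bound is given in its place.

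Before the data were examined, 24 gene lists (551 symbols, 498 of them with a probe) were fixed for sympathetic neuron biology, handling and metabolism, and other cell types, along with the models, the alternatives and the rule for naming genes. The 19 lists with at least 4 tested genes were compared with all other genes by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, which asks whether the genes of a list move one way and does not compare them with other genes. Npy was named first. Of genes past the threshold with the same direction in all 4 mice with both pools, the 12 with the largest difference per direction were to be named, and where fewer passed the 12 were filled with the smallest unadjusted p and given as values. From each tested list came the 2 to 4 members with the smallest unadjusted p. Th, Dbh, Slc18a2, Slc6a2, Chrna3, Phox2b, Chat and Gal were always to be named, as were the 5 genes per direction with the smallest p in the comparison of ages and in the interaction. Predicted and clone-named genes count in totals only, except A330102I10Rik, which was named after its value was seen. Other genes, among them the members of lists named for age, were chosen after their values were seen.

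Alternatives left out background correction, changed the offset to 50, replaced quantile normalization by median scaling or cyclic loess, changed the detection filter, the probe choice, the variance model or the array weights, left out the BeadChip term, used the second deposited table, fitted each BeadChip alone and left out each array in turn. The labels number each pool by its mouse, so equal numbers mark pools of the same animal, and the mouse was fitted as a fixed and as a random block. Deviations from the means of BeadChip and GFP group correlated across genes by -0.14, -0.03, -0.18 and -0.15 between the pools of mice 1, 3, 5 and 6. Fitting those means by itself makes pools of the same BeadChip and opposite GFP status correlate negatively. The negative values therefore do not tell against the pairing. None of the 4 GFP-positive pools with a partner correlated best, among GFP-negative pools, with that of its mouse, which the same fit makes unlikely. The consensus correlation within mice was 0.0010. Correlation of log2 intensity averaged 0.832 over the 4 pairs of pools from the same mouse and 0.815 over the 16 pairs from different mice on the same BeadChip.

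The procedure was tested on simulated data with 200 changed genes among 6234, in 10 simulations. For the GFP comparison 24.9% of 2-fold, 76.0% of 4-fold and 95.9% of 8-fold changes were recovered, with 5.28% of the calls false. For the comparison of ages the shares were 22.4%, 79.7% and 93.8%, with 6.39% of the calls false, and for the interaction 0.149%, 2.99% and 31.4%, with 6.56% false. These shares hold with 200 genes changed at once. With fewer changed genes the Benjamini-Hochberg cut is stricter, so they overstate what a comparison with few calls can find. In the real GFP fit Rxfp1, at 3.66-fold, had adjusted p = 0.818 (limma). Simulated genes were independent, camera with the preset correlation called a list in 0 of 10 such runs without a change, and it called a list lowered by 0.5 in 10 of 10. The residual degrees of freedom of the GFP fit were 7 and the median residual SD was 0.56 on the log2 scale. Signal over background sets what can be seen for each pool, with 3475 to 7131 probes detected at a detection p under 0.01.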

Results

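Expression was measured in neurons of the superior cervical ganglion, the uppermost ganglion of the sympathetic chain, taken from male mice that carry a Renilla GFP reporter controlled by Npy. Npy encodes neuropeptide Y, a peptide that many sympathetic neurons release beside noradrenaline. Dissociated cells had been sorted by hand into pools of 10 GFP-positive or 10 GFP-negative cells, and each pool was amplified and hybridised to its own array of a mouse BeadChip. The 10 arrays held 5 GFP-positive pools, from mice 1, 2, 3, 5 and 6, and 5 GFP-negative pools, from mice 1, 3, 4, 5 and 6, so that 4 of the 6 mice gave both. The pools of mice 1, 2 and 3, aged 4 months, lay on BeadChip 1 and those of mice 4, 5 and 6, aged 7 months, on BeadChip 2, and age and BeadChip cannot be told apart. The comparison at the centre of the design asks which transcripts differ between sympathetic neurons with and without an active Npy reporter. Between 3475 probes (GFP-negative pool of mouse 4) and 7131 probes (GFP-positive pool of mouse 3) out of 45281 were detected per array. Detected probes averaged 6493 ± 475 (SD, n = 5) on the arrays of 4-month mice and 5169.6 ± 1196 (SD, n = 5) on those of 7-month mice, and 5946 ± 967 (SD, n = 5) in GFP-positive and 5717 ± 1335 (SD, n = 5) in GFP-negative pools. The number of arrays limits the precision, and the median standard error of a log2 difference between GFP groups was 0.35.

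Stmn2, which encodes a neuronal regulator of microtubules, and Prph, the intermediate filament peripherin, were detected on 10 of 10 arrays. Uchl1, an abundant neuronal ubiquitin hydrolase, Th, the rate-limiting enzyme of catecholamine synthesis, and Slc6a2, the noradrenaline transporter, were each detected on 9 arrays, and Dbh, which makes noradrenaline from dopamine, on 6. Phox2b, a transcription factor of autonomic neurons, had no named probe on the array. Genes typical of other cells passed the detection filter in part. None of the 19 fibroblast genes and none of the 19 immune genes with a probe passed the detection filter, and 4 of 20 genes of satellite glia and Schwann cells and 4 of 19 genes of endothelial and mural cells did. Of the 7 erythrocyte genes with a probe 3 passed, with the globin gene Hbb-bs on 10 arrays and Hbb-bt on 9. Of 11 genes of chromaffin and small intensely fluorescent cells 6 passed, among them Th and Dbh. Fabp7, a lipid-binding protein of satellite glia, was detected on every array at the same mean log2 intensity of 7.26 ± 0.71 (SD, n = 5) in GFP-positive and 7.26 ± 0.56 (SD, n = 5) in GFP-negative pools.

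Npy was higher in GFP-positive than in GFP-negative pools by 3.12 on the log2 scale (SE 0.37, 95% confidence interval 2.30 to 3.94), or 8.69-fold, and was the single gene past the threshold among the 6234 genes and unnamed probes tested (limma, adjusted p = 0.0216). Npy drives the reporter used for the sort, so this difference checks the labels and is not a finding about the cells. Its mean log2 intensity was 8.79 ± 0.76 (SD, n = 5) in GFP-positive pools, with detection on 5 of 5 arrays, and 5.41 ± 1.03 (SD, n = 5) in GFP-negative pools, with detection on 2 of 5. In the deposited intensities these were 556 ± 278 (SD, n = 5) and 138 ± 71.3 (SD, n = 5). The lowest GFP-positive pool, at 7.63, lay above the highest GFP-negative pool, at 7.18 (mouse 3), although their deposited intensities before normalization were 255 and 264. Npy was higher in the GFP-positive pool of each of the 4 mice with both pools. The exact permutation test over the 252 splits of the arrays into 5 and 5 gave a two-sided p of 0.00794, the smallest that these splits can give. With the mouse as a fixed block, which leaves 4 pairs to carry the comparison, the Npy difference was 3.14 (SE 0.46) and was no longer past the threshold (limma, adjusted p = 0.893). Within BeadChip 1 it was 2.86 (adjusted p = 1) and within BeadChip 2 the fitted value was 3.37 (adjusted p = 0.921), where no GFP-negative pool detected Npy and the difference was at least 6.5-fold. Over 28 alternatives the difference lay between 1.85 and 3.49 with adjusted p from 0.00463 to 1, and 16 of them ended the call. Leaving out 1 pool ended it for the GFP-negative pools of mouse 1 (adjusted p = 0.132), mouse 4 (0.10) and mouse 5 (0.10) and for the GFP-positive pools of mouse 1 (0.0850), mouse 2 (0.0522), mouse 5 (0.138) and mouse 6 (0.0854).

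**Figure D1:**
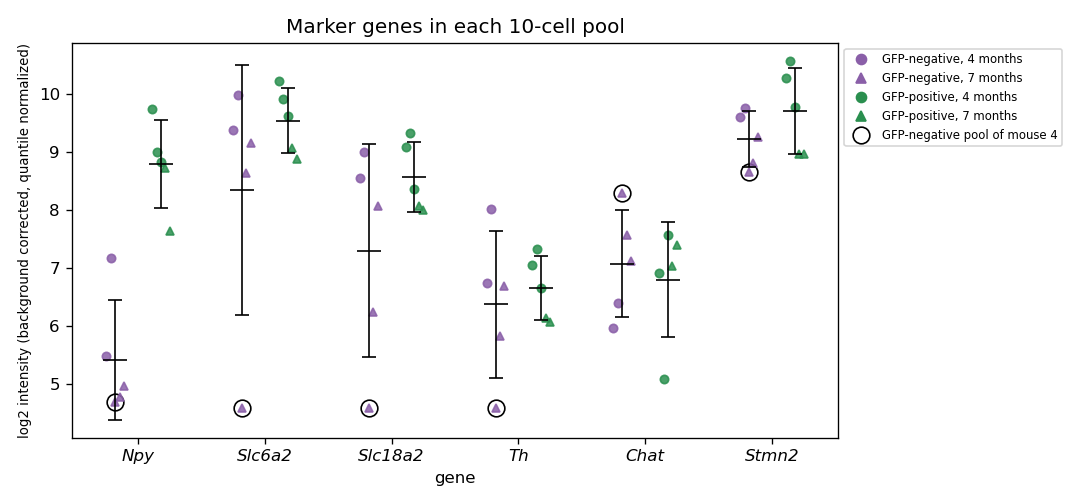
Log2 intensity (vertical axis) of Npy, Slc6a2, Slc18a2, Th, Chat and Stmn2 in each GFP-positive and GFP-negative pool, with circles for 4-month and triangles for 7-month mice, bars for the mean and SD of 5 pools, and a ring around the GFP-negative pool of mouse 4. Npy separates the groups, at 7.63 or more against 7.18 or less, while the GFP-negative pool of mouse 4 lies apart from the other 9 pools for Slc6a2, at 4.58 against 8.63 or more.

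No gene other than Npy differed between GFP-positive and GFP-negative pools past the threshold. The next smallest adjusted p was 0.818, and 223 genes and probes had an unadjusted p under 0.05, where 311.7 would be reached by chance alone (limma). The named genes with the smallest p among those that lay on the same side in all 4 mice with both pools are given as values (adjusted p from 0.818 to 1). Rxfp1, which encodes the relaxin receptor, stood at 6.53 ± 0.81 (SD, n = 5) in GFP-positive pools and 4.62 ± 0.12 (SD, n = 5) in GFP-negative pools, a log2 difference of 1.87 (SE 0.37), with detection on 5 and 1 arrays. P2ry6, a receptor for uridine diphosphate, differed by 2.03 (SE 0.54), with detection on 5 and 2 arrays. Dkk3, a secreted protein of the Dickkopf family, differed by 1.77 (SE 0.47), and by 1.04 at its other kept probe. Akap9, a scaffold that anchors protein kinase A, had a difference of 1.42, with 1.45 and -0.19 at its other probes. Kif2a, a kinesin that takes microtubules apart, had 1.56 at its brightest probe and -0.29 and -0.15 at the others. Maob, monoamine oxidase B, had 1.20 and, at its other probe, 0.16, and Hnrnpa3, an RNA-binding protein, had 1.01 and -0.09. Differences of 1.42 for Nrep, 1.21 for the tetraspanin Tspan18 and 0.97 for Pdp1, a phosphatase that activates pyruvate dehydrogenase, complete the upper side together with Pde3b. Pde3b, a phosphodiesterase of cyclic AMP, was detected on 4 GFP-positive and no GFP-negative arrays, at 5.87 ± 0.69 (SD, n = 5) and 4.66 ± 0.10 (SD, n = 5), which makes it at least 1.43-fold brighter in GFP-positive pools. Such a bound sets the mean of the brighter group against the dimmest detected signal of each array of the other group, or the probe's own signal where that is higher.

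On the lower side, Cplx1, which encodes complexin 1, a regulator of vesicle fusion at the synapse, stood at 6.21 ± 0.59 (SD, n = 5) in GFP-positive and 7.50 ± 0.35 (SD, n = 5) in GFP-negative pools, a log2 difference of -1.38 (SE 0.31). Sugp1, a splicing factor, had -1.54 (SE 0.35) and was detected on 1 GFP-positive and 5 GFP-negative arrays. Fam110b had -1.42, with -1.41 at its other probe, and Fam3c, a secreted protein, had -1.28, with -1.07 at its other probe. P4ha2, a collagen prolyl hydroxylase, had -1.51 at its brightest probe and -0.21 and -0.01 at the others, and Morf4l1, a chromatin protein, had -1.04 and 0.05. Ints6, a subunit of the Integrator complex, had -1.11, Oip5 had -1.16, Pnma2 had -0.85 and Brd2, a reader of acetylated histones, had -0.78. Mtap, an enzyme of methionine salvage, and Spc25, a kinetochore protein, were detected in no GFP-positive pool, with levels at least 1.55-fold and at least 1.41-fold lower there. The other probe of Mtap had -0.64. Mtap averaged 4.63 ± 0.09 (SD, n = 5) in GFP-positive and 5.92 ± 0.62 (SD, n = 5) in GFP-negative pools, and Spc25 averaged 4.50 ± 0.06 (SD, n = 5) and 5.78 ± 0.70 (SD, n = 5).

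Genes of oxidative phosphorylation, the mitochondrial electron transport chain and ATP synthase, were lower as a group in GFP-positive pools, though the list mean was lower in 3 of the 4 mice with both pools and higher by 0.14 in mouse 1. Of 58 tested members 47 lay below 0 and 11 above, with a median log2 difference of -0.29 (limma camera with a preset correlation, adjusted p = 3.11e-07). The call did not hold when the correlation was estimated from the data (adjusted p = 0.677 with an estimated correlation), nor with fry (adjusted p = 0.831). No single member passed over all genes tested, 0 passed adjusted over the list alone, and 7 had an unadjusted p under 0.05 (limma). Ndufv2, a subunit of complex I, had -0.75 (SE 0.25) and was lower in the GFP-positive pool of 4 of 4 mice. Cox5a, a subunit of complex IV, had -0.99 (SE 0.34), Ndufc2, of complex I, had -0.90 (SE 0.32), and Uqcr10, of complex III, had -0.82 with -0.72 at its other probe. Averaged over the list, log2 intensity was 6.44 ± 0.30 (SD, n = 5) in GFP-positive and 6.67 ± 0.26 (SD, n = 5) in GFP-negative pools, a difference smaller than the spread between pools of a group. The list median was -0.27 with the mouse as a block (adjusted p = 3.88e-05), -0.36 within BeadChip 2 (adjusted p = 1.05e-05) and -0.30 within BeadChip 1, where it did not pass (adjusted p = 0.0787). Adjusted p ranged from 1.70e-09 to 0.0787 over 28 alternatives that kept camera with its preset correlation.

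Noradrenergic genes, those for synthesis, storage and uptake of noradrenaline, lay above 0 in GFP-positive pools for 10 of 10 tested members, with a median of 0.57 that did not pass (camera, adjusted p = 0.0587, and adjusted p = 0.677 with an estimated correlation). Slc18a2, the vesicular monoamine transporter, had a log2 difference of 0.94 (SE 0.58), Slc6a2 had 0.88 (SE 0.74) with 0.79 and 0.70 at its other probes, Ddc, which makes dopamine, had 0.67 (SE 0.50) with 0.09 at its other probe, and Th had 0.02 (SE 0.42). None of these 4 genes lay on the same side in all 4 mice with both pools, and 0 members of the list passed over all genes or adjusted over the list alone (limma, 0 with an unadjusted p under 0.05). The GFP-negative pool of mouse 4 had the lowest level of the 10 pools for 8 of the 10 members, with Slc18a2 at 4.59 against 6.24 to 9.33 elsewhere and Th at 4.58 against 5.83 to 8.02. Neither Slc18a2 nor Th was detected in that pool. Without that pool the median was 0.18 (adjusted p = 0.412) and 8 of 10 members lay above 0. The list passed without the GFP-negative pools of mouse 3 (median 0.77, adjusted p = 5.91e-04) and mouse 6 (0.69, adjusted p = 0.00274) and without the GFP-positive pool of mouse 3 (0.61, adjusted p = 0.0289). Within BeadChip 2 the median was 0.87 (adjusted p = 0.0110), within BeadChip 1 it was 0.18 (adjusted p = 0.851), and with the mouse as a block it was 0.21 (adjusted p = 0.463). Adjusted p ranged from 5.91e-04 to 0.851 over 28 alternatives.

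Genes of dense-core vesicles, the organelles that store neuropeptides, lay above 0 for 11 of 13 members, with a median of 0.29 (camera, adjusted p = 0.0633, adjusted p = 0.677 with an estimated correlation and 0.831 with fry). Scg2, which encodes secretogranin II, had a difference of 1.17 (SE 0.43), 0.90 at its other probe and the same side in 4 of 4 mice, and Cpe, a peptide-processing carboxypeptidase, had 0.93 (SE 0.56). No member passed over all genes, and 0 passed adjusted over the list alone (limma, 1 with an unadjusted p under 0.05). This list passed without the GFP-negative pool of mouse 6 (median 0.50, adjusted p = 0.00115) and without the GFP-positive pool of mouse 3 (0.33, adjusted p = 0.0289). It stood at 0.20 within BeadChip 1 (adjusted p = 0.337) and at 0.32 within BeadChip 2 (adjusted p = 0.194). Over 28 alternatives adjusted p ranged from 0.00115 to 0.588.

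The other 16 tested lists did not pass (camera, adjusted p from 0.287 to 0.989). Among G protein-coupled receptors 3 of 6 members lay above 0 and none passed over all genes, but 2 were higher adjusted over the list alone, namely P2ry6 and Adcyap1r1. Adcyap1r1, the receptor for the peptide PACAP, had 0.90 at the probe used and -0.71 and -0.60 at its other probes. Synaptic vesicle genes had 9 of 15 members above 0, a median of 0.09 and 1 member lower adjusted over the list alone, Cplx1, beside 0 over all genes. Syn2, a synapsin, had 0.75 in that list, with 0.38 at its other probe, and Rab3a, a vesicle GTPase, had -0.45, with -0.15. No member passed either way in the remaining lists, in which 7 members had an unadjusted p under 0.05 (limma). Potassium and HCN channel genes had 9 of 12 members below 0 and a median of -0.28, with Kcnip4 at -1.18, where the GFP-negative pool of mouse 1 alone stood at 9.50 and the other 4 at 4.61 to 5.48, and Kcnk1, detected in no GFP-positive pool, at least 1.34-fold lower there. Sodium and calcium channel genes had 8 of 10 members above 0 and a median of 0.13, with Scn3b at 0.44, and -0.13, 0.10 and 0.05 at its other probes. RGS genes, which shorten G protein signals, had 4 of 7 members below 0 and a median of -0.19, with Rgs9 at -1.24 and Rgs7bp at -0.40. Of the sympathetic transcription factors 3 of 8 lay above 0, among them Isl1 at 0.72 in 4 of 4 mice and Tfap2b at 1.10, with -0.10 at its other probe. Ligand-gated channel genes had 3 of 9 members above 0, with Chrna3, the main nicotinic receptor subunit of ganglion neurons, at 1.00 (SE 0.50), with 0.36 at its other probe, and Chrna4 at 0.51. Calcium-binding protein genes had 4 of 10 above 0, with S100a6 at 0.89 in 4 of 4 mice and Hpca at -0.83. Neurotrophic factor and receptor genes had 3 of 6 above 0, with Sort1 at -1.0, with -0.90 at its other probe, and Ngfr at -0.20.

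Among lists of handling, structure and other cell types, ribosomal protein genes had 22 of 44 members above 0, with Rpl12 at 1.23 and Rplp1 at -0.69. Genes of axotomy and dissociation stress had 12 of 20 above 0 and a median of 0.04, with the small heat shock protein gene Hspb1 at -0.82 and Gadd45g at -0.75. Neuronal cytoskeleton genes had 7 of 18 above 0, with Tubb3 at 0.34 and Elavl2 at 0.67, with 0.62 at its other probe, and axon guidance genes had 8 of 17 above 0, with Slit3 at -0.75 and Sema6d at 0.48, or 1.20 and 0.64 at its other probes. The 4 tested genes of satellite glia and Schwann cells had a median of -0.29, with Pmp22 at -0.51 and Fabp7 at 0.03. Those of endothelial and mural cells had a median of 0.06, with Acta2 at -0.36, or -0.09 at its other probe, and Cspg4 at 0.13. Chromaffin and small intensely fluorescent cell genes had 4 of 6 above 0 and a median of 0.05, with Chga at 0.70 and Dbh at 0.62 (SE 0.59), although the median turned to -0.08 with medians scaled and to -0.05 with loess in place of quantiles. Median, mean and test differed in sign for G protein-coupled receptors, transcription factors, ligand-gated channels and calcium-binding proteins (median below 0, mean above 0, test upward), and for neurotrophic factors (median above 0, mean below 0, test downward). They also differed in lists whose median or mean lay within 0.1 of 0, namely ribosomal, endothelial and mural, synaptic vesicle, cytoskeleton and axon guidance genes. Too few genes passed the detection filter for a test of the cholinergic list (2 genes), other neuropeptides (3 genes), erythrocyte genes (3 genes), fibroblast genes (0) and immune genes (0). Of these, Chat, which makes acetylcholine, stood at 6.80 ± 0.99 (SD, n = 5) in GFP-positive and 7.07 ± 0.93 (SD, n = 5) in GFP-negative pools, a difference of -0.06 (SE 0.46), and Ret, a receptor subunit for GDNF family ligands, had 0.38. The neuropeptide genes Gal, Pomc and Tac1 had 0.41 (SE 0.59), -0.08 and -0.22, and the globin genes Hbb-bs and Hbb-bt, with Bpgm of the red cell, had -0.12, 0.14 and -0.05, with 0.18, 0.30 and 0.20 at the other probes of Hbb-bs.

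**Figure D2:**
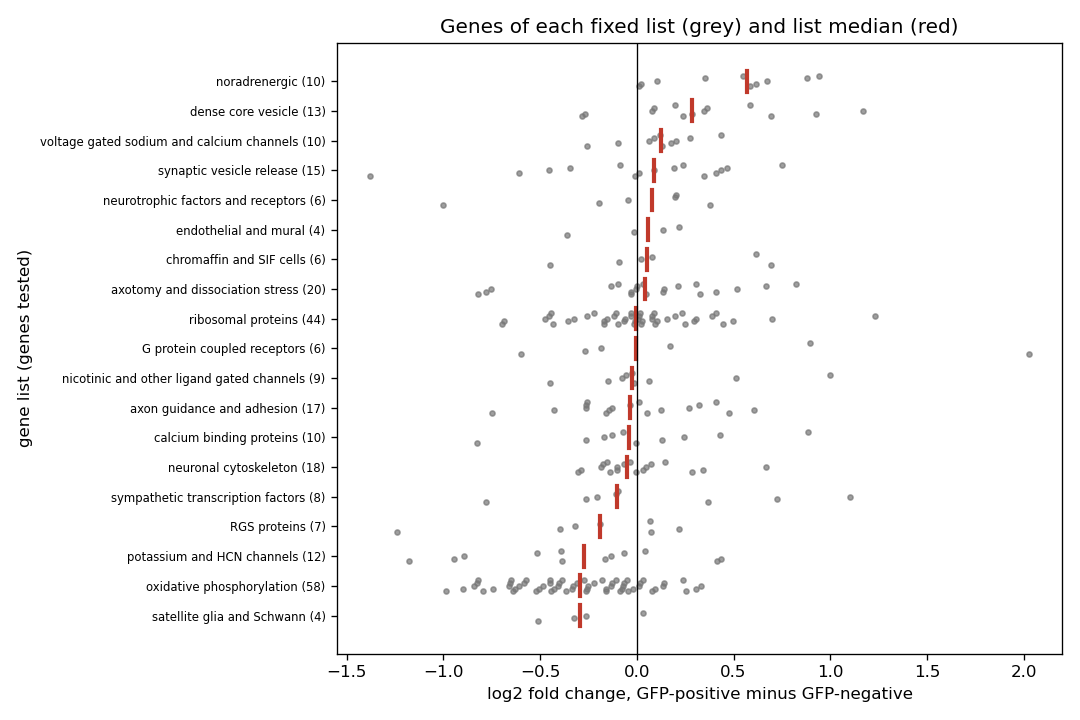
Log2 difference between GFP-positive and GFP-negative pools (horizontal axis) of each tested gene in the 19 fixed lists (vertical axis), with a red mark at each list's median. The oxidative phosphorylation list lies mostly below 0, with 47 of 58 genes there and a median of -0.29, and the 10 noradrenergic genes lie above 0.

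Arrays of 7-month mice on BeadChip 2 differed from arrays of 4-month mice on BeadChip 1 far more widely than GFP-positive from GFP-negative pools. Of 6234 genes and unnamed probes, 664 passed the threshold, 454 higher and 210 lower at 7 months (limma with mouse as a random block), and 1949 had an unadjusted p under 0.05. Among named genes 239 were higher and 182 lower. Since each age lay on a BeadChip of its own, every value here is of age and BeadChip together. Pools of the same mouse counted as nearly independent, since the consensus correlation within mice was 0.0010. The p-values thus measure spread between pools and not between mice or BeadChips. Pdlim3, an actin-associated protein of muscle Z-discs, rose by 2.48 (SE 0.26, adjusted p = 0.00241), from 5.47 ± 0.17 (SD, n = 5) to 7.97 ± 0.40 (SD, n = 5). The chemokine gene Ccl11, which encodes eotaxin, rose by 1.94 (SE 0.22, adjusted p = 0.00241), from 5.36 ± 0.15 (SD, n = 5) to 7.33 ± 0.17 (SD, n = 5). Dtx2, a ubiquitin ligase of the Notch pathway, rose by 2.26, Kif7, a kinesin of Hedgehog signalling, by 2.04, and Hps5, a protein of lysosome-related organelle formation, by 2.16. Trim25, a ubiquitin ligase of antiviral signalling, fell by 2.19 (SE 0.32, adjusted p = 0.00739) and by 1.85 at its other probe, from 7.16 ± 0.25 (SD, n = 5) to 5.06 ± 0.69 (SD, n = 5). Otud4, a deubiquitinase, fell by 1.40 (adjusted p = 0.0192), and Ptbp3, an RNA-binding protein, by 1.43 (adjusted p = 0.0193), with -0.50 at its other probe. Nrsn1, a neuronal vesicle protein, and Snap29, a SNARE protein, were detected on 5 of 5 arrays at 4 months and on none at 7 months, at least 1.93-fold and at least 1.70-fold lower (adjusted p = 0.0138 and 0.0150). Npy itself had -1.27 and missed the threshold (adjusted p = 0.0514).

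The count of genes that differed between ages, and the balance of its directions, depended on single arrays and on the scaling. It was 54 without the GFP-negative pool of mouse 1, 243 without that of mouse 3, 301 without that of mouse 4, 176 without that of mouse 5 and 1137 without that of mouse 6. It was 90 without the GFP-positive pool of mouse 1, 239 without that of mouse 2, 1137 without that of mouse 3, 55 without that of mouse 5 and 28 without that of mouse 6. With medians scaled in place of quantiles the median of all genes moved from -0.06 to -0.38, and 292 genes passed, 40 higher and 252 lower (13.7% higher in place of 68.4%). With no filter on dim probes 170 passed, 82.9% of them higher, and without the mouse as a block 666 passed. With the number of detected probes as a covariate, added after the data had been seen, 0 passed (limma, 1058 with an unadjusted p under 0.05). Over 21 alternatives adjusted p lay between 0.00192 and 0.124 for Trim25, 0.00632 and 0.124 for Nrsn1, 0.00647 and 0.147 for Snap29, 0.00849 and 0.181 for Otud4, and 0.00846 and 0.347 for Ptbp3. Among the 10 genes named above, Snap29, Otud4 and Ptbp3 lost the call without the GFP-negative pool of mouse 1 (adjusted p = 0.0553, 0.0657 and 0.0640). Ptbp3 lost it without the GFP-positive pool of mouse 1 (0.347). Trim25, Nrsn1, Snap29 and Ptbp3 lost it without the GFP-positive pool of mouse 5 (0.0584, 0.0503, 0.0503 and 0.0549), and Nrsn1, Snap29, Otud4 and Ptbp3 without that of mouse 6 (0.0536, 0.0616, 0.0757 and 0.0731).

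The fixed lists were tested on the comparison of ages only after the data had been seen, and 5 of 19 passed, all downward at 7 months (camera with a preset correlation). None of the 5 held when the correlation was estimated (adjusted p = 0.606 for each with an estimated correlation, none with an unadjusted p under 0.05), nor with fry (lowest adjusted p = 0.105). By fry 5 lists had an unadjusted p under 0.05. Sodium and calcium channel genes, upward, were among these and axotomy and stress genes were not. The genes named from the lists were chosen after their values were seen. Oxidative phosphorylation genes lay below 0 for 46 of 58 members, with a median of -0.50, or -0.40 with the 3 members undetected at 7 months set at their bounds (adjusted p = 0.00222), and 4 fell over all genes tested and 3 adjusted over the list alone. Cox5b, of complex IV, fell by 1.30 (adjusted p = 0.0305) and Atp5h, of ATP synthase, by 1.10 (adjusted p = 0.0331). Neuronal cytoskeleton genes lay below 0 for 17 of 18 members, with a median of -0.58 (adjusted p = 0.0154). Of these Gap43, a protein of growing axons, fell by 1.18 (adjusted p = 0.0230) and Stmn2 by 1.01 (adjusted p = 0.0342), with -0.39 at its other probe, while Elavl3, a neuronal RNA-binding protein, rose by 1.40 (adjusted p = 0.0230). The same counts, 1 up and 2 down, passed adjusted over the list alone. Synaptic vesicle genes lay below 0 for 13 of 15 members (median -0.51, adjusted p = 0.0351), and 2 fell over all genes and adjusted over the list alone. These were Syp, which encodes synaptophysin, by 1.86 (adjusted p = 0.0266), and Syt4, a synaptotagmin, by 2.03 (adjusted p = 0.0419), though with -0.03 at its other probe. Genes of axotomy and dissociation stress lay below 0 for 18 of 20 members (median -0.53, or -0.52 with 1 member at its bound, adjusted p = 0.0442), though the 1 member that passed over all genes, Ecel1, a peptidase induced by nerve injury, rose by 1.11 (adjusted p = 0.0364), and 0 passed adjusted over the list alone. Calcium-binding protein genes lay below 0 for 8 of 10 members (median -0.66, adjusted p = 0.0483), and Calm2, a calmodulin gene, fell by 1.13 (adjusted p = 0.0326), with -1.11 at its other probe, over all genes and adjusted over the list alone.

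Noradrenergic genes lay below 0 at 7 months for 9 of 10 members, with a median of -1.20 that missed the threshold (camera, adjusted p = 0.0600, 0.606 with an estimated correlation and 0.222 with fry). The GFP-negative pool of mouse 4, a 7-month pool, had the lowest level of the 10 pools for 8 of the 10 members, though the list passed without that pool, as given below. None passed over all genes, while 5 were lower and 1 higher adjusted over the list alone, with Slc18a2 at -1.69, Ddc at -1.40, or -1.35 at its other probe, Th at -1.30 and Pts, an enzyme of tetrahydrobiopterin synthesis, at 0.86. The 13 other tested lists did not pass (adjusted p from 0.202 to 0.989). Single members of them passed over all genes in both directions, among them Scn3b, a sodium channel subunit, which rose by 1.46 (adjusted p = 0.0451) but had -0.81, -0.21 and -1.37 at its other probes. Slc18a1, the vesicular monoamine transporter of chromaffin cells, rose by 0.98 (adjusted p = 0.0311), and Gria2, a glutamate receptor subunit, fell by 1.28 (adjusted p = 0.0430), with -0.47 at its other probe. Of the lists too small to test, erythrocyte genes lay above 0 for 3 of 3 members, and the globin genes Hbb-bs and Hbb-bt rose by 1.91 (adjusted p = 0.00388) and 1.56 (adjusted p = 0.0230), with 1.82, 1.77 and 1.23 at the other probes of Hbb-bs. In total 25 list genes passed over all genes. Without 1 pool, 1 of the 25 passed when the GFP-negative pool of mouse 1 or the GFP-positive pool of mouse 1, 5 or 6 was left out. Between 6 and 10 passed without the GFP-negative pool of mouse 3 (6), mouse 4 (10) or mouse 5 (7) or the GFP-positive pool of mouse 2 (7). With median scaling or a median shift 9 passed, without a filter on dim probes 4, and with the number of detected probes as a covariate 0.

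Which lists passed in the comparison of ages also depended on single pools. Over 21 alternatives with camera and its preset correlation, adjusted p lay between 1.41e-05 and 0.0592 for oxidative phosphorylation, 2.79e-04 and 0.104 for cytoskeleton, 0.0196 and 0.137 for synaptic vesicle, 0.00354 and 0.619 for axotomy and stress, 0.0111 and 0.217 for calcium-binding protein and 0.0125 and 0.80 for noradrenergic genes. Oxidative phosphorylation lost its call only with the number of detected probes as a covariate, under which 0 lists passed (camera, 5 with an unadjusted p under 0.05). Axotomy and stress and calcium-binding protein genes lost theirs with median scaling (0.0637 and 0.0656), a median shift (0.0764 and 0.101) and detection on 5 arrays (0.0770 for both). Without the GFP-negative pool of mouse 5 the call was lost for cytoskeleton (adjusted p = 0.0524), synaptic vesicle (0.0524), axotomy and stress (0.0780) and calcium-binding protein genes (0.0811). Without that of mouse 3 it was lost for synaptic vesicle (0.0546), axotomy and stress (0.197) and calcium-binding protein genes (0.217), and without that of mouse 4 for axotomy and stress genes (0.111). Without the GFP-positive pool of mouse 1 the same 3 lists missed the threshold (0.0555, 0.0743 and 0.0555), as they did without that of mouse 6 (0.0758, 0.0758 and 0.112), and without that of mouse 2 calcium-binding protein genes did (0.0715). Noradrenergic genes passed in 9 of the 21, among them without the GFP-negative pools of mouse 1 (0.0467), mouse 4 (0.0464) and mouse 6 (0.0392) and without the GFP-positive pool of mouse 5 (0.0249). Ribosomal protein genes passed without the GFP-negative pool of mouse 1 (0.0487, and 0.00663 to 0.80 over the alternatives). With an estimated correlation the ribosomal list did not pass in the model reported (camera, adjusted p = 0.622).

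**Figure D3:**
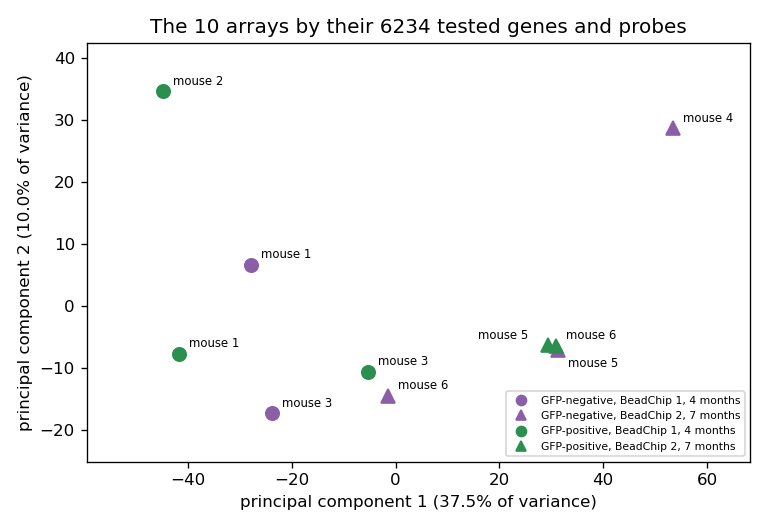
First (horizontal axis, 37.5% of variance) and second (vertical axis, 10.0% of variance) principal components of log2 intensity over the 6234 genes and probes tested, with 1 point per array, colour for GFP status and shape for age. Arrays of 4-month mice lie between -44.8 and -5.38 on the first component and those of 7-month mice between -1.38 and 53.5, while GFP groups overlap on it.

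No gene's difference between GFP-positive and GFP-negative pools differed between 4 and 7 months past the threshold (limma interaction term, 0 of 6234 called, 186 with an unadjusted p under 0.05, smallest adjusted p = 0.999). The median standard error of this term was 0.70. Where all pools of a GFP group were undetected at an age, a bound is given for the genes named here. The Npy difference was 2.86 at 4 months, and at 7 months, where none of 3 GFP-negative pools detected it, Npy was at least 6.5-fold higher in GFP-positive pools, so that the change between ages was not measured. The genes with the smallest p are given as values. Omp, the olfactory marker protein, changed from -0.98 at 4 months to 1.58 at 7 months, by 2.56 (SE 0.67), with 0.30 over both ages and -0.08 at its other probe. Arhgef3, an activator of Rho GTPases, changed from -0.56 to 1.58, by 2.13 (SE 0.59). Gal, which encodes the neuropeptide galanin, had -1.15 at 4 months and was at least 2.15-fold higher in GFP-positive pools at 7 months. Parl, a mitochondrial rhomboid protease, had -1.16 and was at least 2.03-fold higher. Ctnnbip1, an inhibitor of beta-catenin, was at least 1.70-fold higher at 7 months and detected in 1 of 5 pools at 4 months. In the other direction Rnf185, a ubiquitin ligase, had 3.11 at 4 months and was at least 1.5-fold lower in GFP-positive pools at 7 months, while over both ages its GFP difference was 1.03 at this probe and -0.42 and -0.44 at its other probes. Shf had 0.74 at 4 months and was at least 1.79-fold lower at 7 months. Dclk3, a kinase of the doublecortin family, was at least 5.39-fold higher at 4 months and at least 1.52-fold lower at 7 months. Tnc, which encodes the matrix protein tenascin C, was at least 1.65-fold higher at 4 months and had -2.08 at 7 months, with -0.35 over both ages and -0.42 at its other probe. Ccdc92 was at least 2.39-fold higher and had -0.62. With no filter on dim probes 2 genes passed, Tmem254a (adjusted p = 0.0434) and Phactr2 (adjusted p = 0.00561), both named here after their values were seen.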

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

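Both tests of the GFP-negative pool of mouse 4 were chosen only after its values had been seen. Each value given first in this part came from the highest or lowest of the 5 pools of a GFP group and stood apart from the other 4 by more than Dixon's 95% limit allows. Chance alone sets apart about 1 in 20 groups, or 12.4 of the 248 groups of values examined, and 19 were set apart, 6 of them by the GFP-negative pool of mouse 4.

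In the GFP-negative pool of mouse 4, 4 genes lay below the other GFP-negative pools. Slc6a2 stood at 4.58 against 8.63 to 9.98, Maoa, which encodes monoamine oxidase A, at 4.58 against 6.81 to 7.68, Rpl12 at 4.53 against 5.96 or more and Sema6d at 6.59 against 8.75 to 9.17. The values of Slc6a2, Maoa and Rpl12 lay under the dimmest detected signal of that array (5.91) and are background. Above the others lay Sugp1, at 7.56 against 5.94 to 6.35, and Tac1, which encodes substance P, at 7.81 against 4.51 to 5.42. Among the remaining GFP-negative pools, that of mouse 1 had Kcnip4 at 9.50 against 4.61 to 5.48 and Ctnnbip1 at 5.56 against 4.44 to 4.71. Chga was high in the pool of mouse 3, at 6.11 against 4.43 to 4.90, and Fabp7 in that of mouse 5, at 8.22 against 6.83 to 7.20, while Hspb1 was low in that of mouse 6, at 4.99 against 5.94 to 6.17, and A330102I10Rik was high there, at 6.91 against 4.86 to 5.12. Among GFP-positive pools, that of mouse 1 had Ngfr at 10.03 against 8.90 to 9.06 and Kcnh6 at 8.63 against 9.59 to 9.72. The GFP-positive pool of mouse 2 had Chat at 5.09 against 6.91 to 7.57 and Kcnip4 at 5.90 against 4.52 to 4.76. That of mouse 5 had P2ry6 at 6.64 against 8.05 to 8.55 and Rgs10 at 5.62 against 6.51 to 6.80, and that of mouse 6 had Kcnk1 at 5.42 against 4.49 to 4.64. Kcnk1 was detected in no GFP-positive pool, so these values are background. The low values of Hspb1 and Chat also lay under the dimmest detected signal of their arrays (5.17 and 5.27).

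Noradrenergic genes varied between pools of the same GFP group, with a median residual SD of 0.86 at percentile 99.5 of 10000 random lists of like brightness (median 0.59). The wide spread rested on the GFP-negative pool of mouse 4. Without it the SD was 0.45, under the median of the random lists, which were drawn with that pool included. That pool had the lowest level of the 10 pools for 8 of 10 members and detected 2, Pts and Qdpr. The list's median deviation of -1.99 in that pool from the other pools of BeadChip 2 lay at percentile 0 of 10000 lists matched on brightness (median -0.05). Its genes thus lay lower there than others of like brightness. A loss of transcripts of every kind in that pool, which also had the fewest detected probes (3475), stays open. The test cannot decide it, since the pool and the list had been singled out for their low values. Quantile normalization also removes a loss common to all genes. Genes of the neuronal cytoskeleton deviated there by a median of -0.42 (18 genes, 95% bootstrap interval over genes -0.54 to -0.11), which argues against a pool without any neurons. The noradrenergic genes deviated by -1.99 (-2.80 to -0.72), but had been singled out for their low values. Of 77 glial, fibroblast, endothelial and immune genes 6 were detected, against 4 to 11 in the other pools. Of the 77, 3 are also in other lists and 8 passed the detection filter. Fabp7, the brightest glial gene, stood at 6.83 against 6.27 to 8.26. With so few such genes past the filter, the presence of some cells other than neurons stays open. Rab3a (8.35), Prph (6.95), Uchl1 (6.32) and Tubb3 (5.99) lay within the range of the other pools. Isl1 (5.56) did so as well, but was not detected in that pool and was detected in the other 9. Stmn2 (8.65), Gap43 (7.79), Ngfr (8.50), Eya1 (9.42), Chrna3 (4.71), Tfap2b (4.56) and Actb, which encodes beta-actin (8.37, others 8.99 to 10.78), were lowest there. Chrna3 and Tfap2b were not detected in that pool. Neurons of another kind, which the pool may have held, with Chat at 8.29 against 5.09 to 7.57 and Tac1 at 7.81 against 4.51 to 5.58, and loss of single transcripts in amplification stay open, both named after the values were seen and untested. Of the 12 cholinergic genes with a probe only 2, Chat and Ret, passed the detection filter, and Slc18a3, Slc5a7 and Sst were detected on 0 arrays, this pool included.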

How the results depend on the processing

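The number of detected probes as a covariate, the median shift of arrays and the test of lists between ages were chosen only after the data had been seen. Npy stayed higher in GFP-positive pools in all 28 alternatives and past the threshold in 12, with adjusted p from 0.00463 to 1. Past the threshold were, among them, no background correction (0.0257), array weights (0.0229), the second deposited table (0.0322) and the covariate (0.0428). It missed the threshold at 2.90 with median scaling, 2.92 with loess or a median shift, 3.12 without a detection filter or with one at a detection p of 0.05, 3.37 without the BeadChip term, 2.86 and a fitted 3.37 within BeadChips 1 and 2 and 3.14 with the mouse as a fixed block, and lay between 2.85 and 3.49 without 1 array. The count of GFP genes, 1 in the model reported, was 0 in each of these settings (limma, 153 to 766 genes with an unadjusted p under 0.05). Without 1 array it was 0 to 2, with 2 without the GFP-negative pool of mouse 6 (Npy and A330102I10Rik, the second named after its value was seen), 1 without that of mouse 3 or the GFP-positive pool of mouse 3, and 0 without any other. With the detection filter off, 29453 genes and probes were tested, and the fits within a BeadChip and with the block used fewer arrays or degrees of freedom, while for the rest the cause was not tested. The block changed no other call or count by over 1.5 times. The count of lists that differed by GFP, 1 in the model reported, was 0 with an estimated correlation or fry (1 list at an unadjusted p under 0.05 by each) and within BeadChip 1 (camera, 2 lists), 2 with detection on 5 arrays or with mean probes, 3 without the BeadChip term, with array weights, within BeadChip 2 or with the covariate, and 1 to 3 without 1 array, with 2 without the GFP-negative pool of mouse 3 and 3 without the GFP-negative pool of mouse 6 or the GFP-positive pool of mouse 3 (cause not tested). Between ages 664 genes passed, 68.4% of them higher, against 292 with median scaling (13.7% higher), 309 with a median shift (21.7%), 170 without a detection filter, 1192 with array weights and 0 with the covariate (limma, 1058 with an unadjusted p under 0.05). Without 1 array it lay between 28 (GFP-positive pool of mouse 6) and 1137 (GFP-negative pool of mouse 6 or GFP-positive pool of mouse 3), and it changed by over 1.5 times without any 1 of the 10 arrays, as the report gives. The cause of these changes was not tested, though with the covariate the standard errors of the called genes grew and their differences shrank. The count of lists that differed between ages, 5 in the model reported, lay between 0 with the covariate (camera, 5 lists with an unadjusted p under 0.05) and 8 without a detection filter, and was 3 with median scaling, a median shift or detection on 5 arrays. Of the interaction, 20 of 21 alternatives called 0 genes (limma, 119 to 328 with an unadjusted p under 0.05) and 2 passed without a detection filter. For the fixed lists 849 of 905 alternatives counted as the same, 27 lost a call, 26 gained one and 3 moved. For named genes other than Npy 3433 of 3844 counted as the same, 287 lost a call and 124 moved. A value called in neither setting counted as the same when it shifted by less than the residual SD, whichever its sign. For a list this SD was the median over its genes. No direction of a called value reversed. Signal over background limits what can be said of dim genes, since a gene under the detection limit has only a bound.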

Other observations

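The splits for the interaction, the count of BeadChips that hold both ages and the genes named in the next paragraph were chosen only after the results had been seen, and so was the number of detected probes as a covariate. Splits kept the number of pools of each GFP group on each BeadChip.

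Beyond the comparisons, the pools show which transcripts of receptors, channels and regulators were detected, without a test of which cells of a pool they came from. Brightness of different probes does not compare amounts between genes, so detection is given beside that of the brightest kept probe. Of 44 potassium and HCN channel genes with a probe 12 passed the detection filter, with Kcnh6 (mean log2 intensity 9.47) and Kcna6 (8.41) on all 10 arrays. Of 23 sodium and calcium channel genes 10 passed, with the sodium channel subunit genes Scn3b (8.35, but 5.10 to 5.55 at its other probes) and Scn2b (7.41) on 10 arrays. Of 23 ligand-gated channel genes 9 passed, among them Chrna3 (7.31, 9 arrays) and the serotonin receptor gene Htr3a (6.07, 6 arrays). Only 6 of 35 G protein-coupled receptor genes passed, among them P2ry6 (6.82, 7 arrays) and Oprl1, the nociceptin receptor gene (6.27, 10 arrays). Rgs4 (7.53) and Rgs10 (6.54) were each detected on 9 arrays, and the transcription factor gene Eya1 (10.45) and the neurotrophin receptor gene Ngfr (9.22) on 10.

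Of 3 neuropeptide genes past the filter besides Npy, Pomc (7.72) was detected on 10 arrays, Gal (6.04) on 7 and Tac1 (5.24) on 5. Of 30 genes of stress and injury with a probe 20 passed, among them the chaperone gene Hspa8 (9.59), the immediate early gene Egr1 (8.84) and Atf4 (8.45) on 10 arrays. The pools had been dissociated with enzymes and kept in medium for 1 h before lysis, and no pool without these steps was measured.

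Other splits of the 10 arrays were counted for each comparison of groups. For the GFP genes 2 of 100 splits called as many as the real split (1 gene, highest other 2). The count rests on Npy, the gene behind the sort, alone, so these splits check the labels and say nothing about chance for any other gene. For the GFP lists 69 of 100 splits called as many (1 list, highest other 8), and chance cannot be excluded. Some splits called several times the real count, so calls of lists with the preset correlation also arose without regard to GFP status. The cause was not tested. Among the 16 splits that part the 4 pairs of pools from a mouse as the real one does, 1 called as many genes (highest other 0), which is too few splits for a share under 0.05, and 12 called as many lists. For the interaction 100 of 100 splits called as many (0 genes, limma, 186 with an unadjusted p under 0.05, highest other 1), which a count of 0 fixes in advance, so these splits say nothing about chance. Splits of the 6 mice into 3 and 3 number 10 and are too few for a share under 0.05, with 664 genes in the real split, 1 of 10 with as many, and 0 in the highest other.

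Oxidative phosphorylation genes were lower in GFP-positive pools as a list by camera with a preset correlation, and not with an estimated correlation (adjusted p = 0.677) or fry (0.831). Detected probes numbered 5946 ± 967 (SD, n = 5) in GFP-positive and 5717 ± 1335 (SD, n = 5) in GFP-negative pools, a difference smaller than the spread. With that number as a covariate the list kept 100.1% of its median of -0.29. Since the number hardly differed by GFP status, the covariate could hardly move the list, and this fit is no test of its own. A factor shared by the genes of the list that varies between pools irrespective of GFP status stays open and may account for the call, since 7 of 100 splits gave a mean moderated t as far from 0 (real -0.92, largest other 1.22), 3 of them among the 16 that part as many pairs. A difference between GFP-positive and GFP-negative neurons of the same mouse stays open as well, with the list lower in the GFP-positive pool in 3 of 4 mice (0.14, -0.52, -0.23 and -0.62 for mice 1, 3, 5 and 6). The data do not part these explanations.

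Arrays of 7-month and 4-month mice differed in 664 genes. With the number of detected probes as a covariate the called genes kept 89.5% of their median absolute log2 difference (1.30 and 1.16), with the same sign in 664 of 664. Their median standard error grew from 0.30 to 0.38, and 0 genes passed. A different number of detected probes on the arrays of 7-month mice stays open as a cause. The fit cannot part it from age, since that number itself differed between ages (means 6493 and 5169.6) and the genes had been chosen by their differences without it. Normalization between arrays stays open in part, since the lowest count under another background correction or scaling was 44.0% of 664 and the balance of directions turned. A BeadChip, amplification or hybridization batch cannot be told apart from age, since 0 of the BeadChips held both ages. Age itself stays open and untested.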
